A study of Mus musculus with 4 samples.

How the data were processed

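RNA of 4 cell populations of the mouse was measured on Affymetrix gene arrays, with 1 array for each of naive, TT naive, cTh1 and nTh1 cells. Per the labels' protocols, total RNA was extracted with a column kit for small samples, and 300 ng was turned into biotin-labelled cDNA. The deposited values are log2 probe set summaries made by RMA in Affymetrix Expression Console 1.3.1, per the submitters' processing notes. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of a set. The summary level and the annotation version are not given in the sources used here, and scanner files were not used here. All 4 columns were matched to samples by their sample identifiers, and 0 columns stayed unmatched. The table held 41345 probe sets and 0 missing values. The number of arrays limits the precision of every value.

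Probe sets were named from the platform's annotation table. Of them, 23521 had 1 gene symbol, 1814 several and 16010 none in that table, which does not mean that they read no gene. The gene IDs of 23328 probe sets were found in a RefSeq gene table of GRCm38.p6, and 0 symbols differed. That table was used for names only, since the build behind the annotation is not given in the sources used here, and no coordinates are given for that reason. A probe set with several symbols named no gene, and some members of the gene lists were not analysed here. For the 1082 of 22180 genes with more than 1 probe set, the probe set with the highest mean over the 4 arrays was used. Mitochondrially encoded genes had 0 measured members.

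A gene entered a comparison when at least 1 of its arrays was at or above the median of all values, 6.61. Differences are log2 values of the first array minus the second, and genes were counted at 2-fold or more. No test was made and no p-value computed, because each group had 1 array. As the only measure of error, the SD of the log2 difference between probe sets of a gene was taken over genes with 2 or more probe sets above the filter. It covers probe and isoform differences only. The 35 gene lists (T helper programmes, T cell states, metabolism, proliferation, markers of other cell types and RNA quality) were fixed before the data were examined. For each, the median difference over all measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins, and given as a percentile that describes these arrays. Members of a list that passed the filter were counted as at least 2-fold higher, at least 2-fold lower or between. A gene may be in several lists.

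Named genes followed a rule fixed at the same time: in each comparison the 12 highest and 12 lowest genes and the 4 members of each list with the largest difference, any member of the Th1, T-box and sorting lists, the 12 genes shared in each direction, and the 8 highest and 8 lowest differences between comparisons. Predicted and small RNA genes were passed over in naming and kept in the counts. Members of multigene families are named as uncertain. Zbtb16, H2-Aa, H2-Ab1, H2-Oa, Cd79a and Lyz2 are also given in arrays where the rule does not name them, which was chosen after their values were seen.

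Overlaps between comparisons were set beside the number that independent lists would share. Where comparisons shared a control array, 100 draws of unchanged groups were simulated with a noise SD of 0.182 per array. The counting step was tested on simulated data with 22180 genes. For nTh1 over TT naive it recovered 100% of genes planted at a log2 size of 1.5 and 98% at 3, and 0 unplanted genes were called. The noise in that test was a round setting smaller than 0.182 per array. With so little noise hardly any false call was possible, so the test checks the counting step only and not the rate of false calls in the arrays. Alternatives were no level filter, a filter at the 75th percentile, centring, removal of a loess trend with a span of 0.3, the mean of all probe sets, a 3-fold threshold, list members above the filter only, unmatched random lists and omission of cell cycle genes. Baselines with TT naive and the omission of other cell types were added after the data were examined. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.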

Results

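Gene expression was measured in 4 populations of CD4 T lineage cells from mice on the C57BL/6 background at 8 weeks of age, with 1 Affymetrix array per population. Naive cells were sorted as CD4+CD62Lhi from wild-type spleen. Classical Th1 cells (cTh1) were made from such cells by 5 days of culture with beads carrying antibodies to CD3 and CD28, IL-12 at 2 ng/ml, IL-2 at 50 U/ml and an antibody to IL-4. The other populations came from the thymus of mice labelled CIITAtg, a name for a transgene of CIITA, the transcriptional master regulator of MHC class II genes. They were sorted as CD4+CD62L+ thymocytes with CXCR3 (natural Th1, nTh1) or without it (TT naive). CXCR3 is a chemokine receptor carried by Th1 cells. Each array gave log2 values for 41345 probe sets, with medians of 6.57 for naive, 6.64 for TT naive, 6.52 for cTh1 and 6.70 for nTh1. With 1 array per group no difference below has a replicate check, and no p-value is given. The only error that could be measured was the spread between probe sets of the same gene, which leaves out differences between animals, sorts and arrays.

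The genes that define the sorts and the genotype were read first. Cxcr3 stood at 9.91 in nTh1 and 7.76 in TT naive cells, as their sort by CXCR3 requires, and Cd4 lay between 12.33 and 12.72 on all 4 arrays. Ciita gave 7.59, 7.28, 8.00 and 7.72 in naive, TT naive, cTh1 and nTh1, but its probe set may not read the transgene and so checks nothing. MHC class II genes went against a label. H2-Aa was at 12.66 on the array labelled naive, 12.29 in TT naive and 12.66 in nTh1, against 10.73 in cTh1, and H2-Ab1 was at 13.41, 13.06, 13.39 and 12.02. The array labelled naive, which is wild type by its label, thus had these transcripts at the level of both transgenic arrays, with the B cell marker Cd79a at 6.53. The same array had Cxcr3 at 9.80, Tbx21 at 9.81 and Zbtb16, which encodes the PLZF factor of innate-like T cells, at 12.23. From here on it is called the array labelled naive. Every direction drawn from it depends on that label, and so does every direction drawn from nTh1, since a swap of these arrays could not be excluded. The Y-linked transcript Eif2s3y was at 8.61 on the array labelled naive and 8.55 in TT naive, against 4.97 in cTh1 and 5.16 in nTh1, and Kdm5d and Uty split the same way. Xist, transcribed from the inactive X chromosome, was between 12.56 and 13.25 on all 4 arrays. The array labelled naive and TT naive thus carried Xist and Y-linked transcripts together.

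**Figure D1:**
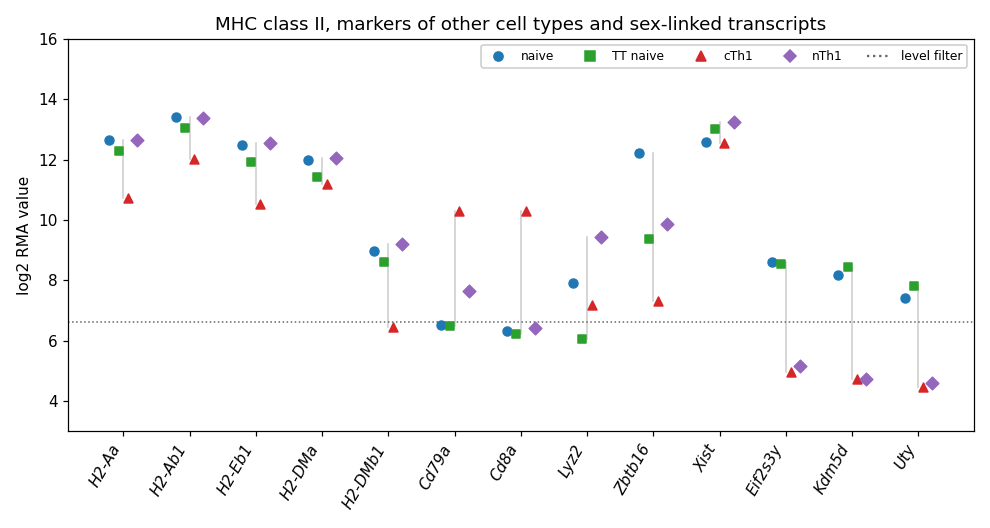
Log2 value (vertical axis) of MHC class II genes, the B cell marker Cd79a, the CD8 chain Cd8a, the myeloid marker Lyz2, Zbtb16 and sex-linked transcripts (horizontal axis), with 1 point per array and a dotted line at the level filter of 6.61. H2-Aa was at 12.66 on the array labelled naive and 10.73 in cTh1, and Eif2s3y was at 8.61 and 4.97.

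Across the 13238 genes at or above the level filter on any array, the most similar arrays were TT naive and nTh1 (Pearson r across genes 0.972) and the array labelled naive and TT naive (0.969). The lowest coefficients were those of cTh1 with nTh1 (0.903) and with TT naive (0.907), and with a filter at the 75th percentile their order turned (0.791 and 0.788). Genes are not independent replicates, so these coefficients describe the arrays only. T cell identity genes such as Cd6, Thy1 and Cd28 differed little. The list median was 0.05 for nTh1 over TT naive and -0.01 for cTh1 over the array labelled naive, and no member differed by 2-fold or more in any of the 4 comparisons.

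The comparison of nTh1 with TT naive cells asks what goes with CXCR3 among thymocytes of CIITAtg mice. Y-linked transcripts differed between these arrays, so the animals behind them differed too. Genes of Th1 and cytotoxic cells were higher in nTh1 cells, and Foxp3 and some other regulatory T cell genes were lower. Nkg7, a granule protein, was higher by 2.56 on the log2 scale, Il12rb2, a chain of the IL-12 receptor, by 2.24, Ccl3 by 1.95, Fasl by 1.75 and Ifng by 1.46. Eomes, the T-box factor of memory-type lymphocytes, was higher by 1.84. Tbx21, which encodes T-bet, was higher by 0.81, under 2-fold. Of 12435 genes above the level filter, 175 were at least 2-fold higher in nTh1 and 136 at least 2-fold lower. The SD between probe sets of a gene was 0.257 for this comparison.

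In the Th1 list, fixed before the data were examined, 7 of 21 members above the filter were at least 2-fold higher in nTh1 and 1 was lower, Ly6c2 at -1.12, a member of a multigene family whose probe set is uncertain. The list median was 0.43, above all 10000 random lists matched on expression (percentile 100). The list of T-box factors and partners had a median of 0.31 (percentile 99.97), with Stat4 higher by 1.52 and Il2rb, the IL-2 receptor beta chain, by 1.04, while Id3, an inhibitor of E proteins that is high in naive T cells, was at -1.77. Small shifts also reached extreme percentiles in this comparison. Small nucleolar RNAs, listed for RNA quality, had a median of 0.07 (percentile 99.98), and histone genes -0.19 (percentile 0.09). Among cytotoxic granule genes and NK receptors, 4 of 13 were at least 2-fold higher, including Prf1, which encodes perforin, at 2.02 and Gzma, a granzyme, at 1.64, and the median was 0.29 (percentile 100). Cd44, the adhesion receptor that marks antigen-experienced cells, was higher by 2.02. The memory-like list as a whole had a median of 0.00 (percentile 81.8), with 4 members at least 2-fold higher and 2 lower. In the innate-like list 3 members were higher, led by Xcl1 at 2.30, and 3 lower, among them Il17rb at -1.35, and Zbtb16 differed by 0.52.

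Immature thymocyte genes were also higher in nTh1 cells. Aqp11 was higher by 2.76, Cd24a, which is shed as thymocytes mature, by 2.19, and Dntt, the terminal transferase of receptor rearrangement, by 2.01. Of 17 members above the filter, 4 were at least 2-fold higher and none lower, with a median of 0.53 (percentile 100). On the other side, Dapl1, a gene of naive T cells, was the lowest of the named genes at -3.83, and Igfbp4 was at -2.06. The naive and quiescent list had 3 of 22 members at least 2-fold lower and a median of -0.10 (percentile 23.6). Foxp3, which specifies regulatory T cells, was at -2.57, and Gpr83 and Tnfrsf9 were at -2.11 and -1.38. In that list 4 of 17 members were at least 2-fold lower and none higher, with a median of -0.22 (percentile 1.69). Follicular helper genes had a median of -0.47 (percentile 0.03), with Il21 at -2.55, Cd200 at -1.61 and Pdcd1 at -1.16. Cholesterol synthesis genes had a median of -0.54 (percentile 0.00), and no member reached 2-fold.

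Markers of other cell types moved with this comparison. The myeloid list had a median of 1.29, with 9 of 16 members at least 2-fold higher, among them Lyz2 at 3.38, C1qb at 2.34 and Mpeg1 at 2.21. The NK list had a median of 0.83 (percentile 100), with 4 of 5 members at least 2-fold higher, among them Tyrobp at 1.75 and Fcer1g at 1.66, and stands beside the Th1, cytotoxic and myeloid genes given here. Of its 9 measured members, 5 are also in another list. The members at 2-fold, Eomes, Tyrobp, Fcer1g and Gzma, are all among these 5, and Tyrobp and Fcer1g are in the myeloid list. The B cell list had a median of 0.61, with Cd79a higher by 1.15. Several of the 12 genes with the largest differences are known from myeloid cells, namely Lilrb4a at 3.53, Ngp at 3.50, Plek at 2.99 and Retnlg at 2.74. Fn1 at 3.10, Pld4 at 2.90, Chst11 at 2.89, Fads2 at 2.79 and Ctla2a at 2.79 were also among them, as was an immunoglobulin kappa variable segment at 2.86, whose probe set is uncertain because the family is large. Lilrb4a was at 11.92 in cTh1 and 8.49 in nTh1, where Lyz2 was at 7.17 and 9.44, so Lilrb4a is not read as a myeloid marker alone. MHC class II genes had a median of 0.41 (percentile 99.99) and no member at 2-fold, beside the myeloid and B cell medians given here. Y-linked transcripts were lower, with Kdm5d at -3.73, Eif2s3y at -3.39 and Uty at -3.19. Other named genes at the low end were Akr1c18 at -3.35, St8sia6 at -2.54, Exph5 at -2.54, Ntrk3 at -2.37, the heat shock gene Hspa1b at -2.25 and Khdrbs3 at -2.25. Without the lists of other cell types and sex-linked transcripts, a choice made after the data were examined, 160 genes were higher and 133 lower. Ngp, Plek, Retnlg and the immunoglobulin segment are in none of these lists and stay in the 160. This omission, here and in the other comparisons, therefore does not measure how much other cells contributed. With a level filter at the 75th percentile of all values, 99 were higher.

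**Figure D2:**
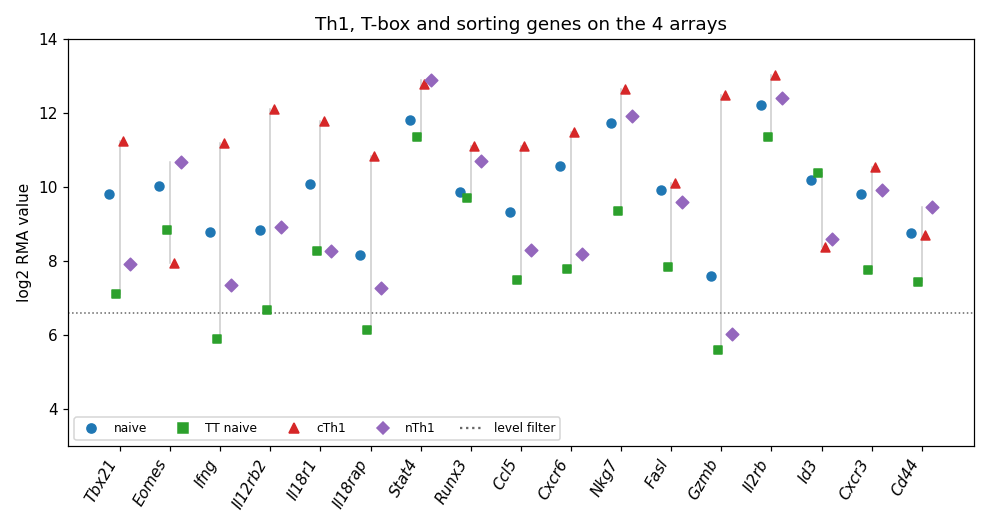
Log2 value (vertical axis) of Th1, T-box and sorting genes (horizontal axis), with 1 point per array and a dotted line at the level filter of 6.61. Tbx21 was at 11.25 in cTh1 and 7.92 in nTh1, and Eomes at 7.94 and 10.68.

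The comparison of cTh1 cells with the array labelled naive asks what differs after Th1 culture, activation included. Th1, glycolysis and cholesterol synthesis genes were higher in cTh1. Gzmb, the cytotoxic protease granzyme B, was higher by 4.89, Il12rb2 by 3.27, Il18rap, a chain of the IL-18 receptor, by 2.68, Ifng by 2.39 and Tbx21 by 1.45. In the Th1 list 12 of 23 members were at least 2-fold higher and none lower, with a median of 1.23 (percentile 100). The array labelled naive itself had Ifng at 8.80 and Tbx21 at 9.81, above the 5.88 and 7.11 of TT naive cells. Against TT naive cells, a baseline chosen after the data were examined, the Th1 median was 2.53. Of 12835 genes above the filter, 659 were at least 2-fold higher and 430 lower than on the array labelled naive, and the SD between probe sets of a gene was 0.402. Among 7020 probe sets without a gene name above the filter, 280 were higher and 514 lower.

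Of the glycolysis genes, 8 of 16 were at least 2-fold higher, with the glucose transporter Slc2a3 at 2.38 and hexokinase 2, Hk2, at 2.14, and the median was 1.09 (percentile 100). Cholesterol synthesis genes had 11 of 14 members at least 2-fold higher and a median of 1.34 (percentile 100), led by Sqle, the squalene epoxidase, at 3.24 and Hmgcs1 at 2.42. The fatty acid desaturases Scd1 and Fads2 were higher by 4.94 and 4.45. Il2ra, the IL-2 receptor alpha chain, was higher by 3.48 and Il10 by 2.87, and 7 of 18 regulatory T cell genes were at least 2-fold higher and 5 lower. Cell cycle genes differed little from the array labelled naive, with a median of 0.22 (percentile 99.9) and 1 of 33 members at 2-fold, Aurkb at 1.03. Against TT naive cells 19 of 33 were at least 2-fold higher and the median was 1.27. Other genes among the 12 highest were Lilrb4a at 5.07, Serpinb5 at 4.86, the interferon-induced Ifitm1 at 4.41, the cell cycle inhibitor Cdkn1a at 4.37, Aldoc at 4.24 and the multigene family member Ly6a2 at 4.33, which is uncertain. Immunoglobulin segments, uncertain for the same reason, were there too, namely a kappa variable segment at 6.22, Igkv4-59 at 4.77 and Iglv1 at 4.53.

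Members of the innate-like T cell list went both ways, with 6 of 18 at least 2-fold lower in cTh1, 4 higher and a list median of 0.08 (percentile 88.6). Il17rb, a receptor for IL-25, was at -5.50, Zbtb16 at -4.91, Il4 at -2.95 and Xcl1 at -2.83. Eomes was lower, at -2.09, and so was Id3, at -1.83. Among MHC class II genes 6 of 10 were at least 2-fold lower, with H2-Eb2 at -4.21 and H2-DMb1 at -2.52, and the median was -1.20 (percentile 0.00). Th2 genes had 4 of 10 members at least 2-fold lower, among them Il13 at -2.84 and the chemokine receptor Ccr8 at -2.85, and 1 higher, and the median of -0.19 (percentile 9.44) turned to 0.20 against TT naive cells. Of genes that follow a recent receptor signal, 9 of 30 were lower and 4 higher, with the early response genes Nr4a1 at -2.38 and Nr4a2 at -2.24. Other genes among the 12 lowest were Nrgn at -5.59, Chl1 at -4.96, Akr1c18 at -4.41, the NK receptor family member Klra9 at -4.38, which is uncertain, Chn2 at -4.07, Cap2 at -4.00, Oas2 at -3.93, Map2 at -3.88 and Eif2s3y at -3.63. Against TT naive cells, 7 of 17 innate-like members were at least 2-fold higher in cTh1 and 4 lower. With that baseline Eomes was at -0.90, under 2-fold, and recent receptor signal genes had 6 of 30 lower and 5 higher.

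The cTh1 array also carried markers of other lymphocytes. The B cell list had 13 of 15 members at least 2-fold higher than on the array labelled naive, with a median of 2.17 (percentile 100), Cd79a at 3.76 and Ms4a1 at 3.35. The CD8 chains Cd8a and Cd8b1 were higher by 4.0 and 2.29, and Gzmk by 3.74, with a CD8 list median of 0.55. The NK list had 3 of 5 members lower and 1 higher. Histone genes, listed as a sign of RNA quality, had a median of 0.37 (percentile 100), and small nucleolar RNAs -0.41 (percentile 0.00). The cell cycle list moved the same way as the histone genes, with a median of 0.22, so the histone value is not read as RNA quality alone. The CD8 values stand beside the Th1 and cytotoxic genes, since Gzmb and Gzmk are also made by CD8 T cells. MHC class II, which B cells carry, was lower in cTh1 while the B cell list was higher. The myeloid list had 4 of 14 members at least 2-fold lower, among them C1qb at -1.98 and Fcer1g at -1.54, and 1 higher. Its median was -0.09 (percentile 14.5). Without the lists of other cell types and sex-linked transcripts, 638 genes were higher and 419 lower.

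The series title sets natural against classical Th1 cells. Th1 effector genes were lower in nTh1 than in cTh1, while Eomes and MHC class II genes were higher. Gzmb was at -6.47, Ifng at -3.85, Il18rap at -3.58, Il18r1 at -3.51, Tbx21 at -3.33 and Cxcr6 at -3.28, and Eomes was higher by 2.74. In the Th1 list 14 of 23 members were at least 2-fold lower and none higher, with a median of -2.52 (percentile 0.00). Stat4, the transcription factor of the IL-12 signal, differed by 0.08, Runx3 by -0.39 and Nkg7 by -0.72. Of 12841 genes above the filter, 444 were at least 2-fold higher in nTh1 and 1066 lower, and the SD between probe sets of a gene was 0.481. The balance was the other way among 8291 probe sets without a gene name above the filter, with 2931 higher and 297 lower. Tissue, genotype and culture differ together here, and cannot be told apart.

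Proliferation and metabolism genes were lower in nTh1. Cell cycle genes had 20 of 33 members at least 2-fold lower and a median of -1.47 (percentile 0.00), with Aurkb at -2.28 and Birc5 at -2.15. Glycolysis genes had 11 of 16 lower and a median of -1.15, and cholesterol synthesis genes had 12 of 14 lower and a median of -1.48. Of the regulatory T cell genes 11 of 18 were at least 2-fold lower and none higher, including Il10 at -3.36 and Ctla4 at -2.51. Inhibitory receptors had 5 of 11 members lower, with Lag3 at -3.30, and 1 higher. Egln3, an oxygen sensor of the hypoxia response, was at -4.71, Cdkn1a at -4.74, Serpinb5 at -5.28, Aldoc at -4.59, Ifitm1 at -4.57 and Slamf7 at -4.45. Prelid2, Car5b, Ak4 and Plod2 were at -4.49, -4.34, -4.22 and -4.20. Lists fixed as signs of RNA quality moved in the same comparison, with 14 of 21 histone genes at least 2-fold lower and a median of -1.06 (percentile 0.00), and 18 of 63 small nucleolar RNAs higher, 4 lower and a median of 0.43 (percentile 100). Histone genes moved the same way as the cell cycle genes, so their shift is not read as RNA quality alone. The B cell list was also lower, at a median of -1.42, as were Cd8a at -3.88 and Gzmk at -4.14.

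Higher in nTh1 were MHC class II genes, with 5 of 10 members at least 2-fold higher, 1 lower, H2-Oa at -1.62, and a median of 1.12 (percentile 100). H2-Eb2 was higher by 3.32, H2-DMb1 by 2.78 and H2-Aa by 1.93. Immature thymocyte genes had 7 of 18 members at least 2-fold higher and 1 lower, with Aqp11 at 2.88 and Sox4, a factor of developing lymphocytes, at 2.67. Interferon response genes had 7 of 25 higher and 4 lower, with the antiviral genes Oasl1 at 2.36 and Ifit1 at 1.96, and Oas2, named by its rank, was higher by 4.31. Nrgn was higher by 3.79, Il17rb by 3.25, Tspan9 by 3.23, Tmie by 2.84, Phxr4 by 2.83 and BC051142 by 2.77. The myeloid list was higher too, with a median of 0.75 and 6 of 16 members at 2-fold, Lyz2 at 2.27 among them, and Ngp and Fn1 were higher by 3.13 and 2.80. Without the lists of other cell types and sex-linked transcripts, 436 genes were higher and 1045 lower.

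The comparison of TT naive cells with the array labelled naive sets the CXCR3-negative thymic population beside the splenic one. Th1, innate-like and cell cycle genes were lower in TT naive cells. Ifng was at -2.91, Cxcr6 at -2.78, Tbx21 at -2.70 and Nkg7 at -2.37, and 12 of 22 members of the Th1 list were at least 2-fold lower against 1 higher, Ly6c1 at 1.66, which belongs to a multigene family and is uncertain. The Th1 median was -1.63 (percentile 0.00). Of 12582 genes above the filter, 100 were at least 2-fold higher in TT naive and 326 lower, and the SD between probe sets of a gene was 0.304. The balance was the other way among 7872 probe sets without a gene name above the filter, with 1372 higher and 118 lower. With a level filter at the 75th percentile, 61 were higher and 217 lower. Without the lists of other cell types and sex-linked transcripts, 99 were higher and 314 lower.

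Cell cycle genes had 16 of 33 members at least 2-fold lower in TT naive and a median of -1.0 (percentile 0.00), with Tpx2 at -1.34 and Plk1 at -1.29. The innate-like list had 7 of 18 lower and none higher, with Xcl1 at -2.96, Zbtb16 at -2.87 and the NK receptor Klrk1 at -2.85. Th2 genes had 6 of 10 lower, among them Il13 at -2.32 and Il4 at -1.60. The memory-like list had 10 of 19 lower, with the calcium-binding S100a6 at -2.08. Ctla2a at -3.01, Cntnap1 at -2.77, Emp1 at -2.70, the chemokine receptor Ccr2 at -2.68, Spry2 at -2.61 and Trpm6 at -2.61 were also among the 12 lowest. Higher in TT naive were genes of naive T cells: 21 of 22 measured members of that list had positive differences, with a median of 0.33 (percentile 100), and Dapl1 reached 2-fold, at 2.21. Cd55 was higher by 2.97, Adam4 by 2.38, Phxr4 by 2.35, Ctse by 2.18, the Notch pathway gene Dtx1 by 1.93 and Hspa1b by 1.64. Slc28a2b, Slc16a5, Ifi214 and Sez6l2 were higher by 1.91, 1.73, 1.68 and 1.66. MHC class II genes had a median of -0.47 (percentile 0.00) with 2 of 10 lower, so the transgenic population was below the array labelled wild type. The myeloid list had a median of -0.69, with 6 of 14 members lower, and the B cell list was at -0.01. The NK list had 4 of 5 members at least 2-fold lower and a median of -1.19 (percentile 0.00), beside the Th1 and innate-like genes given here.

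The last question was whether nTh1 cells differ from TT naive cells in the genes in which cTh1 cells differ from the array labelled naive. Among 13238 genes, 40 were at least 2-fold higher in both comparisons, where independent lists would share 8.71, 56 were lower in both, where they would share 4.42, and 38 went opposite ways, where they would share 12.5. Il12rb2 was higher in both, by 2.24 and 3.27, as were Gzma, by 1.64 and 2.68, and Dntt, by 2.01 and 1.71. Pld4, Ly86, Cybb and Bst1, which are known from B or myeloid cells, and Lilrb4a, Fads2, Gprin3 and P2ry14 were further genes higher in both. Lower in both were Id3 and the Y-linked Kdm5d, Eif2s3y and Uty, and also Akr1c18, Exph5, Ntrk3, Hspa1b, Khdrbs3, Cap2, Chl1 and Irak3. Without the lists of other cell types and sex-linked transcripts, 37 were higher and 53 lower in both. Pld4, Ly86, Cybb and Bst1 are in none of those lists and stay in the 37. Y-linked transcripts were high on both baseline arrays and low in cTh1 and nTh1, so a difference between the animals, their sex included, runs the same way in both comparisons. It cannot be told apart from a shared Th1 change, and leaving out the listed transcripts does not remove it. The submitters' sample descriptions also differ in form, which may mark preparation batches. A batch that separates both baseline arrays from cTh1 and nTh1 would also run the same way in both comparisons. Preparation was not tested as a source of the shared genes, since it cannot be separated from the groups. The correlation of both sets of differences across genes was weak, with Pearson r 0.175 and Spearman rho 0.104.

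With TT naive as the baseline of cTh1 as well, a choice made after the data were examined, 64 genes were higher and 59 lower in both, and 22 went opposite ways. Independent lists would share 12.4, 4.01 and 14.8. Both comparisons then share a control array. Unchanged groups simulated against it shared 0.02 genes upward, had a correlation of 0.500, which the shared control and equal noise on each array fix, and a covariance of 0.0329. That noise came from nTh1 over TT naive, while the probe set spread of cTh1 over TT naive was larger, at 0.440. The simulation also used no level filter, so its values are not directly comparable with the observed ones. The observed correlation was 0.251 and the covariance 0.0666. The simulated noise was the probe set spread, which leaves out animals, sorts and arrays, so no excess over it is read as a shared effect. A single control array cannot be split.

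**Figure D3:**
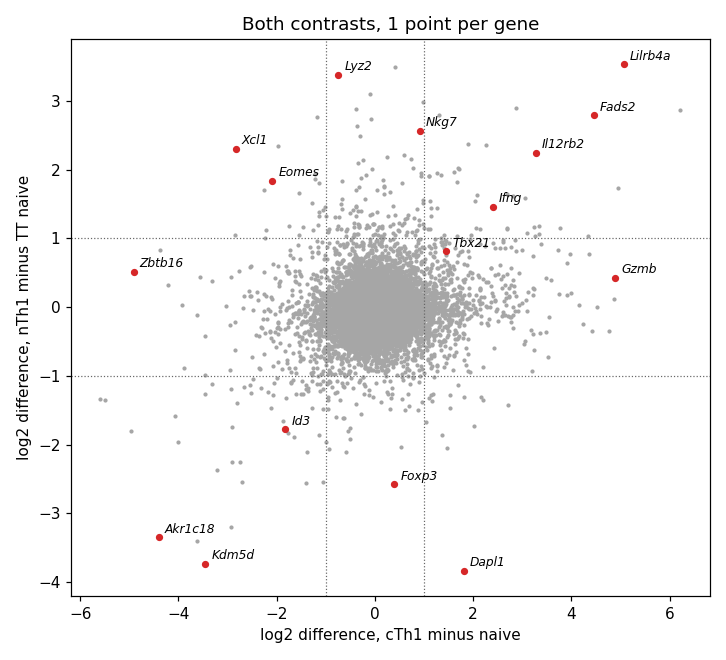
Log2 difference of nTh1 minus TT naive (vertical axis) against that of cTh1 minus the array labelled naive (horizontal axis), with 1 point per gene above the level filter on any array, named genes in red and dotted lines at 2-fold. Il12rb2 lies at 2.24 and 3.27, Eomes at 1.84 and -2.09, and Dapl1 at -3.83 and 1.81.

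The difference between the comparisons was largest in size for Dapl1, at -5.64. The largest positive ones were Zbtb16, by 5.43, and Klra9, by 5.21, followed by Xcl1, H2-Eb2, C1qb, Nrgn, Il17rb and Lyz2, all higher for nTh1 over TT naive than for cTh1 over the array labelled naive. At the other end Dapl1 was followed by Igkv4-59, Ifitm1, Serpinb5, Iglv1, Aldoc, Gzmb and Ly6c1. With 1 array per group these differences of differences were not tested, and each of them uses the array labelled naive.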

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

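All tests of explanations in this part were chosen after the results were seen, except the test of dim probe sets in the block without names, which was fixed beforehand. Bootstrap SDs are over the members of a list and describe these arrays only.

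Some genes moved opposite ways for nTh1 over TT naive and for cTh1 over the array labelled naive, which drew attention to them. With 1 array per group none of these differences was tested. The difference between comparisons was 3.95 for Aqp11, 3.93 for Eomes, 3.91 for Ccr8, 3.24 for Nr4a2 and 5.13 for Xcl1. It was 4.32 for C1qb, 2.47 for C1qc, 3.09 for Clec7a and 3.20 for Fcer1g, all in the myeloid list, with Fcer1g also in the NK list. It was -5.64 for Dapl1 and -3.54 for the inhibitory receptor Lag3. All these opposite directions use the array labelled naive as the baseline of cTh1. Between TT naive and cTh1, Xcl1 (7.05 and 7.18), C1qb (6.64 and 6.61), Aqp11 (7.75 and 7.63) and Clec7a (5.41 and 5.57) hardly differed. Fcer1g (7.09 and 8.03) and Dapl1 (12.11 and 11.70) went the way of nTh1. Lag3 (7.97 and 9.92), Ccr8 (8.96 and 8.10), Eomes (8.84 and 7.94) and Nr4a2 (7.80 and 7.11) stayed opposite. Gene lists were taken here only where the medians had opposite signs and both lay outside the central 95% of their random lists, and they were also not tested. The difference of their medians was 1.61 for MHC class II, -0.85 for regulatory T cells, 0.79 for immature thymocytes, -1.88 for cholesterol synthesis, 1.23 for NK cells, -0.56 for histone genes and 0.48 for small nucleolar RNAs.

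The array labelled naive carried MHC class II genes at the level of the transgenic arrays. RNA of B cells is argued against. The B cell list, for the array labelled naive minus cTh1, had a median of -2.17 (bootstrap SD 0.412) while MHC class II was at 1.20 (0.452). The sign of the B cell value was known, since cTh1 itself carried B cell markers. For the array labelled naive minus TT naive, the B cell median was 0.01 (0.070) while MHC class II was at 0.47 (0.158). RNA of myeloid cells was not tested as a source, and their list had a median of 0.09 (0.295) for the array labelled naive minus cTh1. A swap with the TT naive array is argued against by the sort gene Cxcr3, since cells sorted without CXCR3 would be expected at least 2-fold below nTh1, while the array labelled naive, at 9.80, was 0.11 below it (probe-set SD 0.368) and TT naive had 7.76; the sort reads protein, and MHC class II did not decide this swap, with TT naive minus cTh1 at 0.90 (0.495). A swap with the nTh1 array stays open. MHC class II in nTh1 minus cTh1, at 1.12 (0.491), speaks against it only if culture left these genes unchanged in cTh1. Y-linked Eif2s3y (8.61 on the array labelled naive, 8.55 TT naive, 4.97 cTh1, 5.16 nTh1) and Tbx21 (9.81 on the array labelled naive, 7.92 nTh1) go with it. The thymocyte genes Dntt (6.87 and 9.47) and Aqp11 (8.82 and 10.51) were higher in nTh1 than on the array labelled naive. They do not sort all arrays by thymus and spleen: Dntt was at 7.46 in TT naive and 8.58 in cTh1, and Aqp11 at 7.75 in TT naive. The block without names, described below, was higher in both populations labelled as thymic, but what it reads is not known. Cxcr3 (9.80 on the array labelled naive, 9.91 nTh1) does not tell these arrays apart. None of these values excludes the swap while other cell types on the nTh1 array stay open. A single wrong label, the culture that by design separates cTh1 from the array labelled naive, and a difference between animals also stay open. So does a difference in preparation, which was not tested. MHC class II raised the doubt and so cannot test a wrong label. In the block of probe sets without a gene name TT naive was above the array labelled naive by 0.69. What the block reads is not known, so no label predicts its direction and it cannot test the label either. Zbtb16 was highest on the array labelled naive, at 12.23. The cell cycle list had a median level of 10.12 there, near cTh1 (10.16) and above TT naive (9.13) and nTh1 (8.98).

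Probe sets without a gene name were not part of the gene counts, yet many differed. The 5333 of them that precede the first named probe set had 2395 at least 2-fold higher in nTh1 than in cTh1 and 24 lower, and 1106 higher in TT naive than on the array labelled naive and 9 lower, with array medians of 6.49 (labelled naive), 7.21 (TT naive), 6.21 (cTh1) and 7.49 (nTh1). The named probe sets had a median of -0.024 for nTh1 minus cTh1, against 1.19 in the block. RMA brings the arrays to a common distribution and holds the named median near 0, so this cannot test a shift of the whole array before RMA. The 10012 named ones of similar level were at -0.036, so the block moved apart from named probe sets of its level. These are RMA values too, so a higher background of dim probe sets before RMA is not excluded. Unspliced or nuclear RNA may contribute to the 1.19, and cannot be told apart from other sources, since the tables used do not mark introns. Tissue and genotype go with the arrays that are higher, and a biological difference was not tested.

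Markers of other cell types were seen on the cTh1 and nTh1 arrays and on the array labelled naive, and their source was not tested. The array labelled naive had a myeloid list level of 7.09, between TT naive (6.47) and nTh1 (7.50), with C1qb at 8.59. Its NK list level was 7.66, against 5.94 in TT naive and 7.58 in nTh1. Of the 15 B cell genes above the level filter, 13 were at least 2-fold higher in cTh1 than on the array labelled naive, and Cd79a and Cd8a reached 10.29 and 10.31 in cTh1. The myeloid list had a median of 1.29 for nTh1 minus TT naive, with Lyz2 at 9.44 in nTh1. Of the measured members, 1 of 16 B cell genes and 2 of 18 myeloid genes are in another list. Other cells stay open although the CD4+CD62L+CXCR3+ sort of nTh1 and the CD4+CD62Lhi sort before the cTh1 culture would be expected to remove most of them, and so does expression by the T cells themselves.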

How the results depend on the processing

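Baselines with TT naive and the omission of other cell types were chosen after the data were examined. No paired analysis was possible because each group had 1 array, and for the same reason no array could be left out. At 3-fold, by construction fewer genes passed: 58 higher and 36 lower for nTh1 over TT naive, 271 and 157 for cTh1 over the array labelled naive, 139 and 448 for nTh1 over cTh1, 20 and 91 for TT naive over the array labelled naive, and 14 higher, 16 lower and 6 opposite in both. The filter at the 75th percentile tests fewer genes and left 99 higher for nTh1 over TT naive, 61 higher and 217 lower for TT naive over the array labelled naive, 18 higher in both and 25 opposite, with a Pearson r of 0.195; without a filter r was 0.146. With TT naive as the baseline of cTh1, the Th1 median was 2.53, 64 genes were higher in both and 22 opposite, r was 0.251, and the naive and quiescent list turned from 0.19 to -0.17; the cause was not tested. Lists inside the central 95% of their random lists at the main setting also changed sign: Th17 (-0.07 to 0.55), inhibitory receptors (-0.21 to 0.55), myeloid (-0.09 to 0.29), Th2 (-0.19 to 0.20), gamma-delta (-0.30 to 0.07) and erythroid (-0.09 to 0.08). Counts of single comparisons stayed within 1.5 times of their values after centring, loess removal and averaging of probe sets, as did counts shared by both contrasts after the latter 2, and no list median outside that central 95% changed sign after these 3. No background or detection values were used here, so how far dim genes lie above background is not known.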

Other observations

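Further lists, fixed before the data were examined, are given here as values. Genes of chemokine receptors and homing had medians of 0.07, 0.31, -0.24 and -0.40 for nTh1 over TT naive, cTh1 over the array labelled naive, nTh1 over cTh1 and TT naive over the array labelled naive. In nTh1 the ATP receptor P2rx7 and the integrin chain Itgb7 were lower than in TT naive, at -1.92 and -1.33. Cytokines and chemokines had medians of -0.05, 0.37, -0.57 and -0.46, with Csf1 at -2.79 in nTh1 over cTh1 and Tnfsf11 at -2.52 in cTh1 over the array labelled naive. Th17 genes had medians of 0.17, -0.07, -0.16 and -0.43, with Ccr6 higher by 1.84 in cTh1 than on the array labelled naive. Inhibitory receptors had medians of -0.11, -0.21, -0.55 and -0.32, with Havcr2 higher by 2.56 in cTh1.

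Interferon response genes had medians of 0.03, -0.17, 0.27 and -0.10 in the same order, with Oasl1 at -2.86 and Rtp4 at -2.48 in cTh1 over the array labelled naive. Genes that follow a recent receptor signal had medians of 0.02, -0.46, 0.07 and -0.26. Among other cell types, the dendritic list had medians of 0.10, 0.29, 0.06 and -0.21, the NK list 0.83, -0.40, 0.39 and -1.19, the gamma-delta list 0.10, -0.30, 0.00 and -0.42, and thymic epithelium -0.07, 0.11, -0.25 and -0.01. The erythroid list had 3 measured members and medians of 0.38, -0.09, 0.30 and -0.08. Of the lists that bear on RNA quality, ribosomal protein genes had medians of -0.09, -0.08, 0.01 and 0.01, histone genes -0.19, 0.37, -1.06 and -0.13, and small nucleolar RNAs 0.07, -0.41, 0.43 and 0.02.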
